A study of Mus musculus with 6 samples.

How the data were processed

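The series holds 6 single-cell RNA-seq libraries of mouse large intestine, made as 10x Chromium 5' libraries per the labels. Epithelial cells sorted as CD45-negative and EpCAM-positive came from Foxl1cre; Cxcl12flox/flox mice (called cKO here) and from Cxcl12flox/flox mice (called control), with 1 library of each. Mesenchymal cells sorted as negative for CD45, EpCAM and CD31 and positive for gp38 (podoplanin) came from embryos, neonates, 3-week-old mice and 4-week-old mice, with 1 library per age. The deposited values are raw UMI counts per gene and cell barcode, with Ensembl gene identifiers and no normalization. Cell Ranger 6.0.0 and the mm10 genome build are named in the submitters' processing notes. Each matrix held 32285 genes, of which 32158 matched a gene symbol and 127 did not. No barcode held fewer than 500 UMIs, so barcodes below that total had been left out before deposit. Gene positions are those of GRCm38 (mm10) in the GENCODE annotation, counted from 1.

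All steps after the deposited counts were run here with Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, scanpy 1.11.5, leidenalg 0.10.2, igraph 0.11.9 and matplotlib 3.10.9. TMM scaling factors came from edgeR 4.0.16 in R 4.3.3. Barcodes were kept with at least 1000 UMIs, at least 500 genes and at most 20% mitochondrial UMIs, and doublets called by Scrublet at its automatic threshold were removed. Scrublet marked 738 of 8344 control and 859 of 9513 cKO barcodes. In the mesenchyme it marked 4 of 1487 embryonic, 419 of 9290 neonatal, 212 of 10698 3-week and 161 of 6563 4-week barcodes. Kept cells numbered 7606 in control, 8654 in cKO, 1483 in embryo, 8871 in neonate, 10486 at 3 weeks and 6402 at 4 weeks.

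Cells were clustered on 2000 variable genes, 30 principal components and 20 neighbours with the Leiden method at resolution 1. Both epithelial libraries were clustered together and each mesenchymal library on its own. Genes of the metabolic, stress, sex-linked, mitochondrial, ribosomal and haemoglobin lists, and Cxcl12, were left out of the clustering. A cluster took the name of a class ("X-like") from marker lists fixed before the data were examined. A marker counted when at least 10% of the cluster's cells held it and its level was at least 1 higher on the log2 scale than in the other cells. A name needed at least 3 such markers and at least 40% of the class's list, and no other class could hold more of the cluster's 10 leading genes. Clusters whose median UMI count was under 1/3 of their sample's, with none of the class's markers leading, stayed unnamed. This scoring rule went through 4 versions, each chosen with the cluster tables in view. The 40% minimum was chosen while looking at candidates for the Foxl1-high class, and the results without it are printed beside those that depend on it. A requirement for Foxl1 itself was considered and not used.

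UMIs were summed per library and per class and are given as CPM, counts scaled to the same library total. With 1 library per group no test between groups was possible, and no p-value, standard error or count of changed genes was computed. The design fixed sums with exact Poisson 95% intervals, ratios with exact conditional binomial intervals, and shares with exact Clopper-Pearson intervals. All of these cover counting error only, not differences between animals or collections. Those on UMI counts also treat UMIs of the same cell as independent, and so leave out which cells were sampled. A value of 0 UMIs was bounded at 3 counts. Gene lists were fixed at the same time as the marker lists, 27 for the epithelium and 39 for the mesenchyme. A list is described by the median log2 ratio of its members with at least 50 UMIs over both libraries, by how many members were higher, and by the percentile of that median among 10000 random lists of the same size matched on mean expression in 20 bins. The percentile describes these libraries and is not a test.

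The epithelial genes named are the 10 highest and 10 lowest ratios among genes with at least 200 UMIs and 25 CPM in one library and the same direction in every named class with at least 50 UMIs. To these come 5 each way within the largest named class with at least 200 cells in both libraries, and up to 4 members per list. For the mesenchyme they are the 10 highest and lowest ratios of 4 weeks over embryo, 5 each way for neighbouring ages, and up to 4 members per list. Mitochondrial, ribosomal, haemoglobin, immunoglobulin, T cell receptor, sex-linked and unnamed predicted genes were left out of the ranked parts. Cxcl12, Cxcr4, Ackr3, Foxl1, Pdgfra, Lgr5, Epcam, Pdpn, Ptprc and Pecam1 are always given. Lists were also computed over the mesenchymal classes alone, that is without glia-like, neuron-like, immune-like, endothelial-like, cycling-like and unnamed cells. For shares of cells with a UMI of Foxl1 or Cxcl12, each cell was thinned to 2000 UMIs and shallower cells were left out.

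The count, ratio and list steps were tested on simulated counts. For cKO over control, drawn for 13628 genes, 95.45% of the ratio intervals held the true ratio and 5.00% of 200 unchanged lists had a percentile under 2.5 or over 97.5. Genes changed 0.5-, 0.8-, 1.25- and 2-fold came back at medians of 0.497, 0.807, 1.24 and 1.97. For 4 weeks over embryo, drawn for 14926 genes, 95.45% of intervals held the truth and 1.50% of unchanged lists fell outside. Counts were drawn independently for each gene and unchanged lists at random. These shares therefore do not show how often a list of genes that vary together reaches such a percentile. A list raised 1.25-fold came back at a median log2 ratio of 0.30 for cKO over control and 0.33 for 4 weeks over embryo. The alternatives tried were a stricter cell filter (2000 UMIs, 1000 genes, 10% mitochondrial), no further filter, doublets kept, TMM scaling, CPM without the 20 most abundant genes, means of CPM per cell, a list minimum of 20 UMIs, Leiden resolutions of 0.5 and 2, libraries clustered separately or together, thinning to 1000 and 4000 UMIs, and cells with at least 2 Foxl1 UMIs. Sequence-level work, such as reads over the floxed exon, was not analysed here.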

Results

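Single-cell transcriptomes were collected from the large intestine of mice in which Cxcl12 was deleted from Foxl1-expressing mesenchymal cells, from floxed controls, and from developing mesenchyme. CXCL12 is a chemokine that signals through CXCR4 and is scavenged by ACKR3, and Foxl1 marks mesenchymal cells that lie beneath the epithelium and secrete Wnt and BMP ligands. There was 1 library per group and no replicate, so values are given side by side without a test, and the 95% intervals cover counting error only. The kept epithelial cells were 7606 from the control, with 75666755 UMIs, and 8654 from the cKO, with 90834350 UMIs. The kept mesenchymal cells were 1483 from embryos with 19805734 UMIs, 8871 from neonates with 68413076 UMIs, 10486 at 3 weeks with 66748289 UMIs and 6402 at 4 weeks with 63608271 UMIs. The median cell held 10470 UMIs in control epithelium and 10918.5 in cKO epithelium. In the mesenchyme the median was 11959 UMIs in the embryo, 7134 in the neonate, 6002.5 at 3 weeks and 9919.5 at 4 weeks. Before the filter, 21.9% of control and 16.2% of cKO barcodes exceeded the limit of 20% mitochondrial UMIs, against 4.77% or less in the mesenchymal libraries.

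The deleted gene could not be checked in the epithelial libraries, because the sort removed the cells that carry the deletion. Cxcl12 (ENSMUSG00000061353, chromosome 6, 117168535 to 117181367 on the plus strand of GRCm38) had 7 UMIs in control epithelium and 0 in cKO epithelium, too few to compare. Foxl1 (ENSMUSG00000097084, chromosome 8, 121127940 to 121130644, plus strand) had 0 UMIs in both libraries, which allows a share of up to 0.0347% of cKO cells with a UMI. Of the receptors, Cxcr4 (chromosome 1, 128588199 to 128592293, minus strand) had 5 UMIs in control and 10 in cKO. Ackr3 (chromosome 1, 90203980 to 90216751, plus strand), the only member of the CXCL12 axis list with enough UMIs, stood at 0.819 CPM and 0.738 CPM, a log2 ratio of -0.15 that was 0.36 by means over single cells. Epcam, the epithelial surface protein used in the sort, was at 2143 CPM in control and 2130 CPM in cKO. Pdpn had 0 UMIs in both, Pdgfra 0 and 2, the leukocyte gene Ptprc 14 and 14, and the endothelial gene Pecam1 118 and 109. The Y-linked genes Ddx3y (33.1 and 36.4 CPM) and Eif2s3y (47.9 and 53.2 CPM) were present in both libraries and the female transcript Xist had 3 and 5 UMIs. The sex-linked list had a median log2 ratio of 0.03, and of -0.04 over classes.

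The first comparison asked how epithelial cells, and their metabolism in particular, differ when Cxcl12 is deleted from Foxl1-expressing mesenchymal cells. Lipid synthesis genes were higher in the cKO epithelium: all 18 measured genes of cholesterol synthesis, with a median log2 ratio of 0.43, and all 9 measured genes of fatty acid synthesis, with a median of 0.33. Mvd, which decarboxylates mevalonate diphosphate, stood at 33.7 CPM in control and 56.4 CPM in cKO, a ratio of 1.68 (1.60 to 1.76), and Scd1, the desaturase that makes monounsaturated fatty acids, at 15.9 and 32.5 CPM, a ratio of 2.04 (1.91 to 2.19). All 13 respiratory chain genes encoded by mitochondrial DNA were lower in the cKO, with a median of -0.22. Slpi, a secreted inhibitor of neutrophil proteases, had the highest ratio of the genes ranked, at 19.02 CPM in control and 60.9 CPM in cKO, 3.20-fold (3.02 to 3.40), and Sst, the gene of the hormone somatostatin, the lowest, at 37.7 and 5.42 CPM, 6.97-fold lower (6.33 to 7.68). Sst was among the leading genes of a cluster of only 75 control and 51 cKO cells, and its interval leaves out which cells were sampled. The median of all 13638 measured genes was -0.02.

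The cholesterol synthesis list lay at percentile 100 of matched random lists. Percentiles near an end were not rare among the lists, with serine and one-carbon genes at 99.94 and goblet mucus genes at 0.04. Fdps, which makes farnesyl diphosphate, was 166 CPM in control and 269.5 CPM in cKO, 1.62-fold higher. Hmgcs1, which makes HMG-CoA for the pathway, was 162 and 246 CPM, and Lss, the enzyme that closes the sterol ring, 18.7 and 28.0 CPM. Fatty acid synthesis genes also lay at percentile 100. Scd2 was 341 CPM in control and 488 CPM in cKO, Fasn, the fatty acid synthase, 49.0 and 67.1 CPM, and Acaca, which makes malonyl-CoA, 22.7 and 28.5 CPM. Within cell classes the median for cholesterol synthesis was 0.74 in colonocyte-like, 0.49 in stem-like and 0.31 in cycling-like cells, but -0.11 in goblet-like and -0.05 in enteroendocrine-like cells. The colonocyte-like class drew on clusters in different proportions, with 946 control and 641 cKO cells in 1 cluster and 105 and 306 in another, and within its 4 clusters the median lay between 0.21 and 0.62. Fatty acid synthesis followed a like order, with 0.57 in colonocyte-like, 0.44 in cycling-like, 0.34 in stem-like, 0.06 in goblet-like and -0.38 in enteroendocrine-like cells, where 5 genes were measured. Within single clusters of at least 50 cells, the cholesterol list was above 0 in 19 of 22 and the fatty acid synthesis list in 15 of 21. Mvd lies on chromosome 8 (122433601 to 122443422, minus strand), Scd1 on chromosome 19 (44394455 to 44407879, minus strand), Hmgcs1 on chromosome 13 (119690379 to 119708260, plus strand) and Slpi on chromosome 2 (164354070 to 164389095, minus strand).

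**Figure D1:**
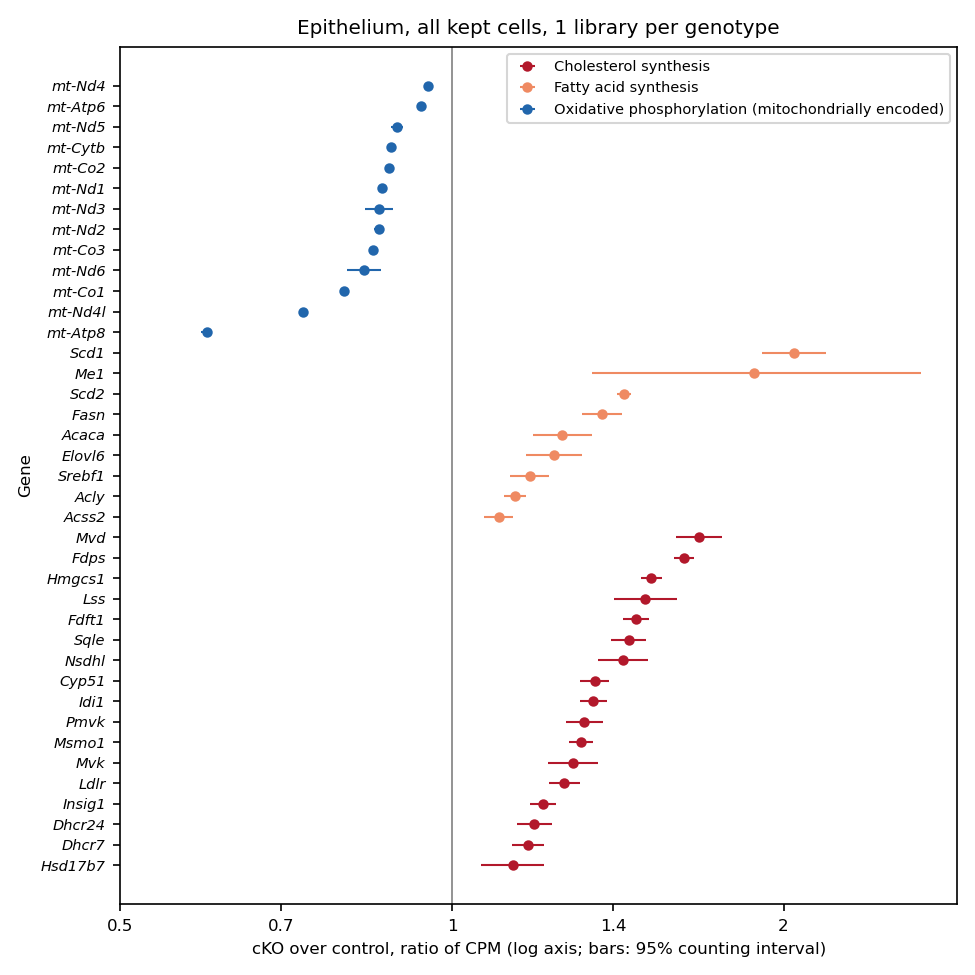
Ratio of CPM in cKO over control epithelium (x axis, log scale) for measured genes (y axis, 1 cholesterol synthesis gene not drawn) of cholesterol synthesis, fatty acid synthesis and the mitochondrially encoded respiratory chain, with points for all kept cells of 1 library per genotype and bars for the 95% counting interval. The cholesterol and fatty acid synthesis genes drawn all lie right of 1, and all 13 mitochondrially encoded genes lie left of it.

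Over all kept cells, genes of energy metabolism other than lipid synthesis differed by less, as judged by list medians. In goblet-like cells the mitochondrially encoded list, at -0.19, differed by more than cholesterol synthesis (-0.11) or fatty acid synthesis (0.06). Of the mitochondrially encoded genes, mt-Co1, a core subunit of cytochrome oxidase, was 11409 CPM in control and 9106 CPM in cKO, mt-Nd4l 1398 and 1024 CPM, mt-Nd6 80.5 and 67.0 CPM, and mt-Atp8, a subunit of ATP synthase, 916 and 549 CPM. This list lay at percentile 0 of random lists and was below 0 in 20 of 22 clusters, with a class median of 0.23 in the small tuft-like class and between -0.26 and -0.10 in the others. The share of barcodes with high mitochondrial content and the median mitochondrial share of kept cells, 4.22% in control and 3.37% in cKO, differed in the same direction. Both rest largely on the same UMIs as the list and are not a separate observation. Of nuclear-encoded respiratory chain genes 50 of 59 were higher, with a median of 0.04 (percentile 43.2), led by Ndufa4 at 354 and 445 CPM. Glycolysis had 10 of 15 members higher (median 0.08), with Gapdh at 396 CPM in control and 545 CPM in cKO and Eno1 at 104 and 130.3 CPM. By means over single cells the glycolysis median was not above 0 (-0.00). Within classes the glycolysis median ran from -0.04 in goblet-like to 0.27 in cycling-like cells, and was 0.50 in the small tuft-like class. The citric acid cycle list had a median of -0.00 (0.04 over classes), with the citrate synthase gene Cs at 338 and 308 CPM. Fatty acid oxidation and ketogenesis had 16 of 23 members higher, with a median of 0.05, and Pdk4, a kinase that restrains pyruvate oxidation, was 2.72 and 4.87 CPM. In colonocyte-like cells this list had 22 of 23 members higher and a median of 0.24. It stood at 0.06 in cycling-like, 0.03 in goblet-like, -0.02 in stem-like and -0.12 in enteroendocrine-like cells, and above 0 in 11 of 22 clusters. Serine and one-carbon genes had a median of 0.15 over all cells and -0.03 as the median over classes, with Psat1 at 3.61 and 5.94 CPM and Phgdh, the first enzyme of serine synthesis, at 10.2 and 15.3 CPM. Hypoxia response genes had a median of -0.00 (0.02 over classes) and went both ways, with Ankrd37 at 14.96 and 9.71 CPM and Car9 at 26.5 and 34.7 CPM.

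Among absorptive genes higher in the cKO, Clca4a, a colonocyte marker, was 22.4 CPM in control and 46.0 CPM in cKO, and Fabp2, an intestinal fatty acid carrier, 92.4 and 187 CPM. Wfdc18 (15.9 and 29.9 CPM), Ddah1 (23.7 and 43.3 CPM), the interferon-induced antiviral gene Ifitm3 (29.7 and 54.4 CPM) and the actin-capping gene Capg (20.9 and 36.5 CPM) complete the higher genes of the ranking. The lower genes held several transporters and enzymes of differentiated cells: Fxyd4, a regulator of the sodium pump, at 155 and 55.9 CPM, Slc37a2, itself a marker used to name colonocytes, at 108 and 45.1 CPM, Slc15a1, a peptide transporter, at 35.0 and 17.4 CPM, Rbp2, a retinol carrier, at 66.9 and 34.6 CPM, and Tgm3, a transglutaminase, at 823 and 488 CPM. Cyp2d12 (26.1 and 12.7 CPM) and the anion channel Best2 (70.2 and 41.9 CPM) were also lower. Fxyd4, Tgm3 and Slc37a2 were among the leading genes of a colonocyte-like cluster of 498 control and 402 cKO cells. Slc15a1 was among those of a cluster of 946 and 641 cells, Fabp2 of 105 and 306, and Clca4a of 79 and 146. Tgm3 and Fabp2 also led other clusters. These ratios therefore do not tell a difference within cells from a difference in cluster proportions. The absorptive transport list had a median of -0.08 over all cells, with the sodium channel subunits Scnn1g (3.79 and 1.398 CPM) and Scnn1b (8.91 and 4.13 CPM) lower and carbonic anhydrase Car1 (916 and 1198 CPM) higher. Within colonocyte-like cells its median was 0.06.

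Hormone genes were lower over all epithelial cells, beside a lower share of enteroendocrine-like cells. The enteroendocrine list had 7 of 9 members lower and a median of -0.46, while within the enteroendocrine-like class (118 control and 93 cKO cells) its median was 0.38. Sst and Ppy, the pancreatic polypeptide gene (30.8 CPM in control and 5.83 CPM in cKO), were lower within that class too, at log2 ratios of -2.08 and -1.49. Gcg, the proglucagon gene, was 129 and 69.2 CPM over all cells and -0.05 within the class, and Pyy, the peptide YY gene, 827 and 527 CPM and 0.19 within the class. The goblet mucus list had a median of -0.17 over all cells and 0.02 within goblet-like cells, with the angiogenin Ang4 at 21.1 and 7.46 CPM, the mucus protein Clca1 at 1306 and 916 CPM and Retnlb at 1.59 and 3.57 CPM. Tuft cell genes had a median of -0.26, with Dclk1 at 2.99 and 2.07 CPM, and 0.25 within the tuft-like class. In these small classes the goblet mucus list was higher too, at 0.89 in enteroendocrine-like cells (10 of 10 measured members) and 2.99 in tuft-like cells (8 of 8). Within goblet-like cells the highest ratios were those of Slpi (94.2 CPM in control and 345 CPM in cKO), B4galnt1 (9.16 and 26.7 CPM), Cmah (14.7 and 38.2 CPM), Mt3 (18.7 and 48.5 CPM) and Plet1 (27.5 and 65.2 CPM). The lowest were those of Ang4 (117 and 42.6 CPM), Edn1 (27.7 and 11.7 CPM), Krt83 (30.9 and 13.7 CPM), Rbp2 (45.0 and 20.1 CPM) and Scnn1b (45.4 and 20.9 CPM). Plet1, Mt3 and Cmah were among the leading genes of a goblet-like cluster that held 181 control and 429 cKO cells, and Slpi among those of another that held 304 and 195.

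Stress, immune and signalling lists completed the epithelial comparison. Unfolded protein response genes had 10 of 13 members higher, a median of 0.16 and a median above 0 in 22 of 22 clusters, with the chaperone gene Calr at 219 and 274 CPM, Manf at 162 and 198 CPM, and the stress factor Ddit3 lower at 56.3 and 45.4 CPM. The immediate-early and heat shock list was below 0 in 20 of 22 clusters (median -0.10 over all cells), and its parts differed: Fosb was 867 and 619.7 CPM, while the inducible heat shock genes Hspa1a and Hspa1b were 41.6 and 65.2 CPM and 48.6 and 72.4 CPM. Interferon response genes had 14 of 19 members higher and a median of 0.11, with Isg15 at 4.16 and 6.12 CPM. Genes of MHC class II had a median of 0.26 over all cells and -0.03 as the median over classes, with H2-Aa at 1.67 and 2.65 CPM and H2-Ab1 at 7.27 and 5.24 CPM. Proliferation genes had 12 of 19 members higher (median 0.08; -0.09 over classes), with the replication gene Mcm3 at 17.7 and 23.6 CPM. The Wnt target and stem cell list had a median of 0.04 over all cells but -0.11 over classes, and was below 0 in 14 of 18 clusters, with Cd44 at 6.54 and 9.92 CPM, Ccnd1 at 52.5 and 69.3 CPM, Ascl2 at 15.9 and 11.5 CPM and Lgr5 at 9.26 and 7.84 CPM. BMP response genes had a median of 0.07, and -0.03 by means over single cells, with Id1 at 803 and 722 CPM. Host defence genes had a median of -0.08, with the neutrophil chemokine Cxcl2 at 15.1 and 25.01 CPM. Fetal-like and regenerative genes had a median of 0.07 over all cells and -0.15 over classes, from 0.54 in colonocyte-like to -0.70 in tuft-like cells, with Ly6a at 127 and 161 CPM and Clu at 6.63 and 4.00 CPM. Of mesenchymal transcripts only Dcn was measured, with 0 UMIs in control and 72 in cKO, all in 1 cell. The haemoglobin and immune cell lists had no measured member.

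Stem-like and cycling-like cells made up larger shares of the cKO library and colonocyte-like cells a smaller one. With the main cell filter, the smaller colonocyte-like share came by way of a cluster with low UMI counts. Stem-like cells were 7.64% of control and 10.5% of cKO cells, a ratio of 1.37 (1.23 to 1.52), and cycling-like cells 9.03% and 11.2%, a ratio of 1.24. Colonocyte-like cells were 21.4% and 17.3%, a ratio of 0.807, and this class held the cluster with a median of 2292 UMIs, close to the minimum of 1000. That cluster held 12.4% of control and 7.41% of cKO cells, with median mitochondrial shares of 11.9% and 11.6%. The other colonocyte-like clusters held 6.55% and 4.65%, 1.38% and 3.54%, and 1.04% and 1.69%. Outside the shallow cluster the class was thus not a smaller part of the cKO library with this filter. With the stricter filter, colonocyte-like cells were still 12.6% of control and 10.3% of cKO cells. The part played by shallow cells is therefore not settled. Goblet-like cells were 20.7% and 18.7%, a ratio of 0.901 that was 1.03 when the libraries were clustered separately. Enteroendocrine-like cells were 1.55% and 1.07%, and tuft-like cells 0.355% and 0.3004%. Unnamed clusters held 39.3% of control and 41.0% of cKO cells. The largest was led by Krt36 and the chemokine gene Cxcl1 and held 12.4% of control and 15.3% of cKO cells. Genes that differed between the libraries, such as Slc37a2 and Plet1, were among the leading genes of clusters.

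The second comparison followed the sorted mesenchyme from embryo to 4 weeks. Matrix, complement and cytokine genes were higher at 4 weeks than in the embryo, and fetal growth genes, cell cycle genes and cholesterol synthesis genes were lower. Dcn, the collagen-binding proteoglycan decorin, stood at 1178 CPM in the embryo, 6794 in the neonate, 7157 at 3 weeks and 7546 at 4 weeks. Dlk1, an imprinted gene of fetal progenitors, was 1299, 365, 4.94 and 0.204 CPM at the same ages. The library content differed as well: in the embryo 14.3% of cells were glia-like and 18.3% neuron-like, against 1.05% glia-like cells and no neuron-like cluster at 4 weeks. The median of all 14570 genes was -0.47 for 4 weeks over embryo by CPM and 0.11 after TMM scaling, so list medians for the mesenchyme are given relative to the median of all genes, while counts of higher members are by CPM.

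Fibrillar collagen and matrix genes had 15 of 16 members higher at 4 weeks than in the embryo and a relative median of 2.52. Mgp, an inhibitor of calcification, was 121, 527, 2319 and 2121 CPM at the 4 ages, and elastin (Eln) 187, 557, 1593 and 1142 CPM. Complement had 8 of 9 members higher (3.95), with the protease gene C1s1 at 20.7, 179, 392 and 515 CPM and C4b at 0.252, 6.37, 36.3 and 68.7 CPM. Chemokines and cytokines had 14 of 16 members higher (2.58). The B cell survival factor Tnfsf13b was 0.707, 3.27, 54.7 and 105 CPM, Il6 was 2.12 CPM in the embryo and 61.2 CPM at 4 weeks, and the monocyte chemokine Ccl8, with 1 UMI in the embryo, was 565-fold higher (101 to 22322). Growth factors for epithelium had 9 of 10 members higher (2.51), with the EGF receptor ligand Ereg at 7.12, 16.4, 82.5 and 108 CPM and Hgf at 7.68 CPM in the embryo and 48.2 CPM at 4 weeks. Basement membrane genes had 9 of 12 members higher (1.43), with perlecan (Hspg2) at 65.7 and 367 CPM and nidogen-2 (Nid2) at 44.5 and 11.7 CPM. Over the mesenchymal classes all 5 lists were also above all genes, growth factors at 1.30 and basement membrane at 0.87, and matrix, complement, cytokine and growth factor genes lay at percentile 100 of matched random lists in all kept cells.

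Genes of fetal growth and of the cell cycle were lower at 4 weeks than in the embryo. All 12 imprinted growth genes were lower at 4 weeks (relative median -3.15), with H19 at 346, 48.6, 1.95 and 0.204 CPM, the growth factor Igf2 at 253, 27.9, 3.07 and 2.42 CPM and Mest at 607, 198, 24.0 and 10.3 CPM. All 7 fetal growth regulators were lower (-5.58), among them the chromatin protein Hmga2 at 40.8, 3.87, 0.285 and 0.0943 CPM and Sox11 at 204, 25.04, 8.64 and 3.08 CPM. All 19 proliferation genes were lower (-3.19), with the mitotic kinase Cdk1 at 75.7, 35.6, 15.6 and 4.73 CPM. All 18 cholesterol synthesis genes were lower (-1.004), with Cyp51, the lanosterol demethylase, at 177, 72.6, 24.5 and 34.7 CPM and Sqle, the squalene epoxidase, at 113, 40.2, 15.8 and 28.6 CPM. This list was also lower in each earlier step and 18 of 18 members were higher at 4 than at 3 weeks, with a relative median of 0.44. Glycolysis had 1 of 15 members higher (-0.77), with Pfkl at 105, 25.2, 16.8 and 16.1 CPM and the glucose transporter Slc2a1 at 103, 40.6, 15.9 and 17.7 CPM. Each of these 5 lists was below all genes over the mesenchymal classes as well.

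**Figure D2:**
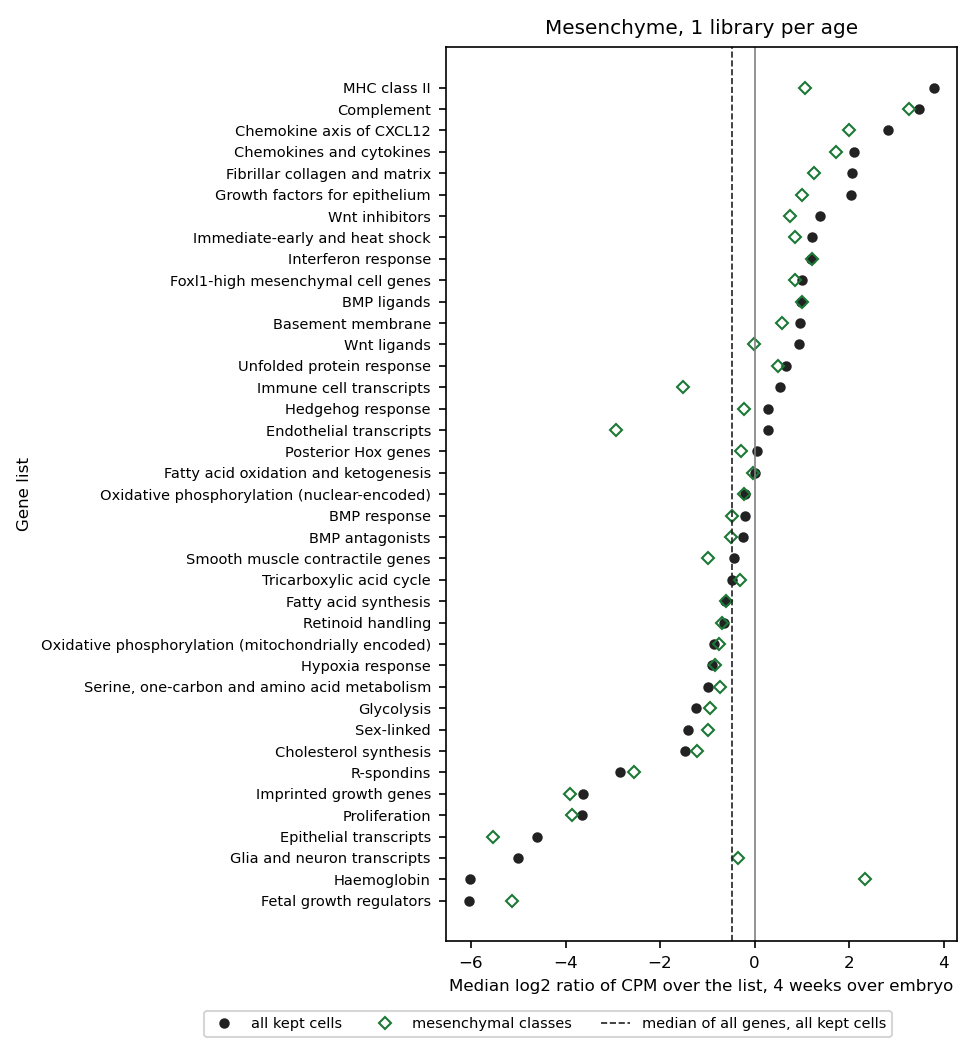
Median log2 ratio of CPM, 4 weeks over embryo (x axis), for each gene list (y axis), with filled circles for all kept cells, open diamonds for the mesenchymal classes and a dashed line at the median of all genes in all kept cells (-0.47), 1 library per age. Fetal growth regulators and haemoglobin lie farthest left in all kept cells (-6.05 and -6.03), and MHC class II and complement farthest right (3.79 and 3.48).

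Genes that signal to the epithelium went different ways. The Foxl1-high list had 13 of 14 members higher at 4 weeks (1.46), with Bmp5 at 23.9, 25.5, 133 and 218 CPM, Bmp4 at 141, 396, 758 and 869 CPM, and tissue factor (F3) at 45.3, 26.6, 75.1 and 218 CPM. Most of that difference lay between neonate and 3 weeks (0.97), and from embryo to neonate the list stood at 0.10, or -0.90 over the mesenchymal classes. BMP ligands had 7 of 8 members higher (1.45), with Gdf10 at 30.4, 181, 37.0 and 14.4 CPM as the exception. BMP antagonists had 4 of 8 higher (0.22, and -0.20 over the mesenchymal classes), with gremlin (Grem1) at 14.996, 74.3, 98.1 and 132 CPM and follistatin (Fst) at 39.0 CPM in the embryo and 9.12 CPM at 4 weeks. BMP response genes stood at 0.26, and at -0.19 over the mesenchymal classes, with Id3 at 724 and 1506 CPM. Wnt ligands had 6 of 8 higher (1.41, and 0.27 over the mesenchymal classes), with Wnt2b at 7.78 and 66.3 CPM and Wnt5a at 49.99 and 98.3 CPM. R-spondins, which amplify Wnt signals, stood at -2.37, with Rspo1 at 23.7 and 3.32 CPM and Rspo2 at 9.85 and 1.26 CPM, while Rspo3 at 22.0 and 20.5 CPM had a ratio of 0.931 (0.834 to 1.04), above the median of all genes. Wnt inhibitors had 6 of 8 higher (1.85, and 1.03 over the mesenchymal classes), with Wif1 at 0.404, 0.175, 7.58 and 13.6 CPM and Dkk2 lower at 20.5 and 2.94 CPM. Hedgehog response genes stood at 0.76, and at 0.06 over the mesenchymal classes, with Hhip at 46.2 and 179 CPM and Gli3 at 92.7 and 48.1 CPM. Retinoid genes went both ways (-0.17), with Rbp4 at 5.10, 79.999, 399 and 327 CPM and the retinoic acid receptor Rarb at 35.4 and 3.51 CPM.

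Interferon response genes had 18 of 20 members higher at 4 weeks (1.66), with Bst2 at 50.5, 61.7, 167 and 254 CPM and Ifit3 at 7.68, 7.50, 25.2 and 45.6 CPM. From embryo to neonate this list was 0.33 over all cells and -0.55 over the mesenchymal classes. Genes of MHC class II stood at 4.26, and at 1.35 over the mesenchymal classes, with Cd74, the invariant chain, at 1.31 CPM in the embryo and 40.9 CPM in the neonate. Cd74 and H2-Aa led the immune-like clusters found at the 3 later ages, and the embryo had no such cluster. Immediate-early and heat shock genes had 15 of 16 members higher (1.69), with Hspa1b at 51.6, 191, 988 and 1563 CPM, a group that tissue dissociation also induces. Unfolded protein response genes had 14 of 14 higher (1.13), with Herpud1 at 71.5 and 137 CPM, and 12 of 14 higher at 4 than at 3 weeks (0.51). Mitochondrially encoded genes had 0 of 13 higher (-0.38), with mt-Nd6 at 104 and 32.8 CPM. Nuclear respiratory chain genes stood at 0.27, with 17 of 59 higher by CPM and Atp5k at 205 and 106 CPM. The citric acid cycle stood at -0.01, fatty acid oxidation at 0.47 with Bdh1 at 16.6 and 1.07 CPM, fatty acid synthesis at -0.15 with Scd1 at 9.19 and 26.9 CPM and Scd2 at 231 and 71.9 CPM, serine and one-carbon genes at -0.52 and hypoxia response at -0.43. Posterior Hox genes, which set regional identity, stood at 0.52, with Hoxa11 at 15.05 and 33.3 CPM and Hoxd13 at 13.5 and 5.39 CPM. Smooth muscle contractile genes stood at 0.03, and at -0.71 over the mesenchymal classes, with desmin (Des) at 150.4 and 30.3 CPM and Lmod1 at 20.6 and 46.3 CPM.

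Among the genes ranked without lists, the carboxylesterase Ces1d had 0 UMIs in the embryo and was 0.687, 47.1 and 59.8 CPM later, at least 395-fold higher at 4 weeks. Ly6c1 and Ly6a, surface antigens of adventitial fibroblasts, were 0.353 and 210.1 CPM and 2.78 and 1306 CPM in embryo and 4 weeks. Hsd11b1, which regenerates active glucocorticoid, was 0.202, 2.62, 51.6 and 91.8 CPM, and Pcolce2, which enhances collagen processing, 0.454, 7.54, 69.8 and 95.9 CPM. The calcium store gene Casq2, with 3 UMIs in the embryo, was 192-fold higher (65.5 to 931), and the clock gene Npas2 was 0.252, 2.60, 10.8 and 29.3 CPM. The lowest ratios were those of neuronal genes, beside a neuron-like class found only in the embryo: Snap25, of the synaptic vesicle machinery, was 45.9 CPM in the embryo with 0 UMIs at 4 weeks, at least 973-fold lower. Fstl5, Zfp804a, Tlx2, Kcnq3, Nefl, Gria2, Nrg3 and Ralyl had 0 UMIs at 4 weeks, with bounds from at least 1221-fold lower for Fstl5 to at least 535-fold lower for Ralyl. Glia and neuron transcripts as a list stood at -4.54, and at -0.05 over the mesenchymal classes, with the neuronal tubulin gene Tubb3 at 244 and 2.70 CPM. Epithelial transcripts stood at -4.13, with Epcam at 16.0, 0.906, 0.734 and 0.236 CPM. Haemoglobin transcripts stood at -5.56, with Hbb-bs at 495, 16.9, 11.6 and 6.78 CPM, and were 2.63 above all genes over the mesenchymal classes. Endothelial and immune transcripts stood at 0.75 and 1.01, and both were below all genes over the mesenchymal classes (-2.64 and -1.22). The sorting genes Pdpn (80.03, 101, 167 and 213 CPM), Ptprc (1.31, 1.75, 1.89 and 1.57 CPM) and Pecam1 (2.78, 2.92, 2.88 and 4.09 CPM) were present in all libraries, with Pdpn highest at 4 weeks. Pdgfra, the fibroblast receptor, was 71.6, 164, 234 and 323 CPM, and Lgr5 was 4.39 CPM in the embryo and 0.0786 CPM at 4 weeks. Sex-linked genes stood at -0.95, and Xist (351 and 130.1 CPM) and Uty (18.1 and 6.10 CPM) were present in embryo and 4-week libraries.

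Between neighbouring ages, the neonate had more Ccl19, a lymphoid chemokine (1.01 CPM in the embryo and 54.5 CPM in the neonate), Scn7a (1.06 and 27.2 CPM) and Clec3b (60.4 and 1361 CPM) than the embryo. It had less of the neuropeptide gene Cartpt (69.4 and 0.190 CPM), of Myt1l (25.9 and 0.117 CPM) and of the keratins Krt8 (60.6 and 0.263 CPM) and Krt7 (36.4 and 0.205 CPM). At 3 weeks, besides Ces1d, Hsd11b1, Tnfsf13b and Ccl8, Lgals3 was higher than in the neonate (3.70 and 66.5 CPM), and besides Dlk1 and H19, Col9a2 (83.0 and 1.20 CPM), Fabp7 (114 and 5.27 CPM) and Kif21a (58.6 and 3.51 CPM) were lower. At 4 weeks the highest ratios over 3 weeks were those of Stmn2 (3.91 and 30.4 CPM), Plac9b (16.5 and 57.3 CPM), the adventitial gene Pi16 (49.2 and 171 CPM), Gda (11.9 and 38.6 CPM) and the chaperone Sdf2l1 (13.9 and 42.4 CPM). The lowest were those of the clock output gene Dbp (43.9 and 7.22 CPM), the clock repressor Nr1d2 (27.7 and 4.84 CPM), Cpz (91.9 and 17.4 CPM), and the growth factors Mdk (425 and 117 CPM) and Ptn (128 and 35.9 CPM).

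The third comparison asked whether Foxl1-high mesenchymal cells are a source of Cxcl12 and from which age. Cxcl12 was 152 CPM (146 to 157) in the embryo, 952 (945 to 960) in the neonate, 1313 (1304 to 1321) at 3 weeks and 1440 (1431 to 1449) at 4 weeks, 9.50-fold higher at 4 weeks than in the embryo and 5.98-fold over the mesenchymal classes. Foxl1 itself was far scarcer, at 14.6 CPM (13.0 to 16.4), 11.5 (10.7 to 12.3), 17.5 (16.5 to 18.6) and 19.4 (18.3 to 20.5), and its 4-week over embryo ratio of 1.33 was 0.863 over the mesenchymal classes. At 4 weeks the Foxl1-high-like class had the highest Cxcl12 level of the named classes, 2302 CPM, against 997 CPM in the other mesenchymal classes, 2.31-fold (2.27 to 2.35). It held 37.0% of all Cxcl12 UMIs and 23.1% of the UMIs of all genes. Unnamed clusters, which are in neither group, had 1471 CPM, with 30.4% of Cxcl12 UMIs and 29.7% of the UMIs of all genes. The 2 clusters of the Foxl1-high-like class differed, with 997 cells at 2478 CPM and 264 cells at 1709 CPM, the latter below lamina propria fibroblast-like cells. At every age other classes carried Cxcl12 as well, with lamina propria fibroblast-like cells at 2167 CPM at 4 weeks. The 997 CPM joins these with 1315 trophocyte-like cells at 328 CPM and 576 smooth muscle-like cells at 472 CPM. Trophocyte-like cells had 1474 CPM in the neonate and 511 CPM at 3 weeks, so the level of the other classes also shapes how the ratio differs with age.

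In the younger libraries the Foxl1-high-like class was less set apart. It stood at 1511 CPM against 1214 CPM in the other mesenchymal classes at 3 weeks, 1.24-fold (1.22 to 1.27), where lamina propria fibroblast-like cells had 2305 CPM and 28.4% of the Cxcl12 UMIs and unnamed clusters, which are in neither group, 1454 CPM and 39.7%. In the neonate the values were 754 and 812 CPM, 0.929-fold (0.838 to 1.03), with 37 lymphoid stroma-like cells at 2413 CPM, trophocyte-like cells at 1474 CPM and smooth muscle-like cells at 1319 CPM, while unnamed clusters held 39.6% of the Cxcl12 UMIs at 1569 CPM. The cluster with the highest Cxcl12 was unnamed at both ages. It had 400 cells at 2676 CPM in the neonate, with 34.3 CPM of Foxl1, and 876 cells at 2717 CPM at 3 weeks, with 6.53 CPM of Foxl1. In the embryo they were 305 and 236 CPM, 1.29-fold (1.11 to 1.4996), with adventitial-like cells at 507 CPM and lamina propria fibroblast-like cells at 325 CPM. When clusters were named with no minimum share of markers, the ratio was 2.02 in the neonate and 0.577 in the embryo, and when the libraries were clustered together it was 2.45 in the embryo, so the embryonic and neonatal ratios rest on how the class is drawn. Cells with a Foxl1 UMI had 2.43 times the Cxcl12 of cells without one in the embryo (2.24 to 2.63), 1.49 times in the neonate (1.45 to 1.53), 0.898 times at 3 weeks (0.879 to 0.918) and 1.21 times at 4 weeks (1.19 to 1.23). The embryonic value was 1.41 over the mesenchymal classes, that is without neuron-like, glia-like, cycling-like and unnamed cells, which had 0.932, 3.51, 146 and 189.9 CPM of Cxcl12. A Foxl1 UMI was found in 38.7% and 22.2% of cells of the 2 Foxl1-high-like clusters at 3 weeks, and in 36.5% and 34.1% at 4 weeks. Most of that class thus counts as without one. A smooth muscle-like cluster held 19.4% of Foxl1 UMIs at 3 weeks, with 223 CPM of Cxcl12. Another held 15.2% at 4 weeks, with 147 CPM. How far this mix sets the 3-week ratio was not tested.

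Foxl1 is 1 of the 12 markers that name the Foxl1-high-like class, so its share there is partly set by the naming. That class held the largest part of Foxl1 UMIs at 3 and 4 weeks, 48.8% and 64.9% at 64.9 and 54.4 CPM, followed by smooth muscle-like cells, with 21.2% and 16.5% at 32.9 and 40.5 CPM. In the embryo lamina propria fibroblast-like cells held 54.7% of Foxl1 UMIs at 45.0 CPM and the Foxl1-high-like class 28.0% at 125 CPM. In the neonate unnamed clusters held 48.5% of them, smooth muscle-like cells 31.1% at 38.6 CPM and the Foxl1-high-like class 4.85% at 73.9 CPM. After thinning to 2000 UMIs per cell, Cxcl12 was found in 15.3% of embryonic, 59.2% of neonatal, 72.4% of 3-week and 73.3% of 4-week cells, against 0.505%, 4.52%, 11.2% and 6.78% of glia-like cells. In the few immune-like cells it was found in 36.7% in the neonate, 36.6% at 3 weeks and 28.6% at 4 weeks, so glia-like cells alone do not bound the background. Foxl1 was found in 2.32%, 2.52%, 3.09% and 2.75%, against 1 of 951 glia-like cells in the neonate and 0 of 198, 188 and 59 in embryo, 3 weeks and 4 weeks, which allows up to 1.52%, 1.60% and 5.08%. Median depths before thinning were 12543.5, 6033, 4000.5 and 4700 UMIs in glia-like cells. Of the other genes of this axis, Ackr3 was 41.6, 43.2, 145 and 217 CPM and Cxcr4 at most 0.858 CPM, and the list stood at 3.28 for 4 weeks over embryo.

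**Figure D3:**
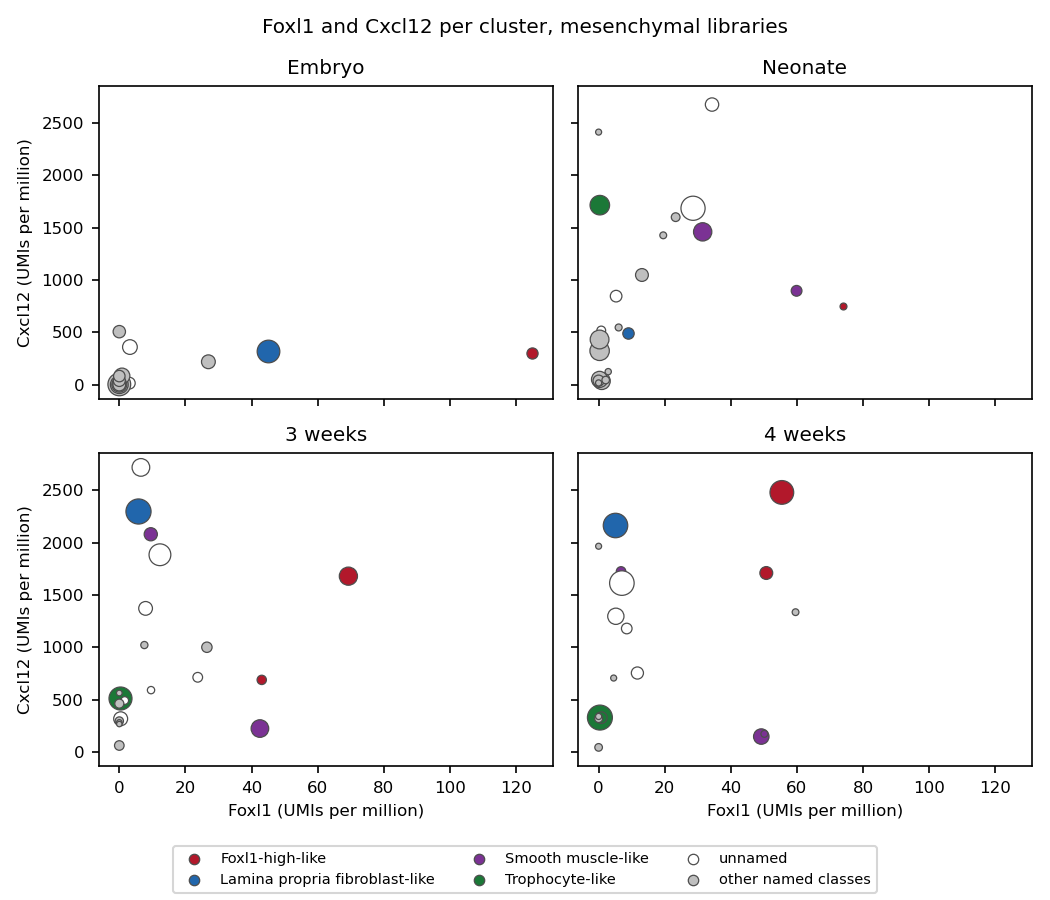
Cxcl12 (y axis) against Foxl1 (x axis), both in CPM, for each cluster of the 4 mesenchymal libraries, with circle area growing with the share of cells and colour giving the class. At 4 weeks the Foxl1-high-like clusters (class level 54.4 for Foxl1 and 2302 for Cxcl12) stand high on both axes, and in every library clusters with little Foxl1 also have Cxcl12 UMIs.

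The make-up of the mesenchymal libraries differed with age. Trophocyte-like cells, which secrete gremlin near crypt bases, were 12.1% of neonatal, 14.6% of 3-week and 20.5% of 4-week cells. The 4-week share joins clusters of 17.3% and 3.23%. With the libraries clustered together, trophocyte-like clusters held 13 and 4 neonatal, 1589 and 739 3-week, and 1089 and 282 4-week cells. An adventitial-like cluster then held 1960 neonatal cells, so the neonatal share and the order of ages depend on how the libraries are clustered. No embryonic cluster was named trophocyte-like, although an unnamed one of 83 cells held 3 of the 7 markers, with Dpt and Cd34 among its leading genes. Foxl1-high-like cells were 2.97%, 0.755%, 10.8% and 19.7% at the 4 ages. Their small neonatal cluster was led by haemoglobin genes and then by Bmp7, Bmp3 and Sox6. With no minimum share of markers the embryonic and neonatal shares were 7.35% and 16.9%, and with the libraries clustered together 19.4% and 2.76%, so no order of embryo and neonate against 3 weeks can be read. The 4-week share was the highest in these settings, at 23.4% with the libraries clustered together. The 40% minimum keeps out a neonatal cluster of 1434 cells led by Wnt4 and Adamdec1, which held 37.9% of neonatal Foxl1 UMIs. Lamina propria fibroblast-like cells were 14.2%, 3.10%, 17.5% and 16.6%. The neonatal ones were 1 cluster with a median of 3005 UMIs led by Neat1, while neonatal clusters of 1434 and 400 cells nearest to this class stayed unnamed. Smooth muscle-like cells were 2.76%, 11.7%, 12.7% and 9.00%, and pericyte-like cells 3.17%, 10.2%, 2.19% and 1.19%, with 25 of those at 3 weeks in a cluster led by Chgb, Pcp4 and Chga. With the libraries clustered together, the largest pericyte-like cluster held 38 embryonic, 1058 neonatal, 15 3-week and 1 4-week cells. The name may thus not cover the same cells at each age. Interstitial cell of Cajal-like cells, the pacemakers of gut movement, were 6.47%, 7.39%, 1.37% and 0.422%. Glia-like cells were 14.3%, 11.1%, 2.02% and 1.05%, and cycling-like cells 8.97%, 7.41%, 2.48% and 0.687%. Adventitial-like cells were 3.78% and 9.51% in embryo and neonate and had no cluster of their own later, where trophocyte-like clusters of 1528 cells at 3 weeks and 1108 cells at 4 weeks also had 6 and 4 of the adventitial markers. Mesothelial-like cells were 3.51% in the embryo. Immune-like cells were at most 0.868% and endothelial-like cells at most 0.406%. Unnamed clusters held 21.6%, 25.5%, 35.2% and 29.9%, and 8.35% of 3-week cells would take a name at a lower marker threshold of 0.5.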

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

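The alternatives with another marker threshold, with no minimum share of markers and with medians over clusters were chosen only after the results were seen, as were the lists that lead the report, and the other alternatives were planned. Ratios of the ranked genes kept their direction in every alternative run: 160 values for cKO over control, 160 for 4 weeks over embryo, and 79, 80 and 80 for the neighbouring ages. These genes were picked for extreme ratios, and the epithelial ones also for the same direction in every named class. Keeping direction was therefore largely set by how they were picked. Counts of members of the leading lists stayed within 1.5-fold in 36 epithelial and 90 mesenchymal values, a wide limit for lists picked after the results were seen. The epithelial list medians ranged from 0.26 to 0.46 for cholesterol synthesis, from 0.28 to 0.39 for fatty acid synthesis and from -0.30 to -0.12 for mitochondrially encoded genes. TMM scaling and CPM without abundant genes turned no epithelial list median whose interval left out 0. Mesenchymal medians are relative to all genes, so such a scaling cannot move them. For all values below, the cause was not tested. No paired analysis was possible because each group had 1 library. Depth limits Foxl1, with a UMI in few cells, and small classes such as tuft-like cells.

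Sign changes of list medians are given one by one only where the 95% counting interval of the reported median left out 0. Of the other epithelial medians, over all alternatives, Wnt targets ranged from -0.20 to 0.12, fetal-like genes from -0.18 to 0.18, sex-linked genes from -0.13 to 0.056, the citric acid cycle from -0.047 to 0.078, hypoxia response from -0.20 to 0.086 and the CXCL12 axis from -0.27 to 0.36. Epithelial medians set apart from 0 that changed sign were these. By means over single cells, glycolysis was -0.0048 and BMP response -0.035. As the median over named classes, serine and one-carbon genes were -0.030, proliferation -0.087, MHC class II -0.033, goblet mucus 0.047 and tuft genes 0.25. At a Leiden resolution of 0.5 these class medians were -0.57 for MHC class II, 0.0091 for absorptive transport, 0.047 for goblet mucus and 0.24 for tuft genes, and at 2 they were -0.0048 for serine and one-carbon genes, -0.22 for MHC class II, 0.090 for goblet mucus and 0.25 for tuft genes. As the median over clusters, fatty acid oxidation was -0.0028, proliferation -0.038, BMP response -0.038, goblet mucus 0.068, host defence 0.0062 and enteroendocrine hormones 0.75.

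Mesenchymal list medians, relative to all genes, changed sign mainly over the mesenchymal classes. Medians whose interval held 0 are not listed, such as endothelial transcripts, from -0.22 to 0.84 for 3 weeks over neonate and from -0.17 to 0.19 for 4 over 3 weeks, or hypoxia response, from -0.088 to 0.11 for 3 weeks over neonate. For 4 weeks over embryo these gave BMP response -0.19, haemoglobin 2.63, immune transcripts -1.22, BMP antagonists -0.20, smooth muscle -0.71 and endothelial transcripts -2.64. With classes named without a minimum share, BMP response was -0.16, haemoglobin 2.55, posterior Hox -0.20, smooth muscle -0.56 and endothelial transcripts -2.35. For neonate over embryo the mesenchymal classes gave interferon -0.55, haemoglobin 3.69, Wnt ligands -0.34, Hedgehog -0.25, basement membrane -0.12 and growth factors -0.53. Without the minimum share these were -0.45, 3.81, -0.46, -0.25, -0.0015 and -0.051, with retinoid genes at -0.063 and epithelial transcripts at 0.29, and by means over cells smooth muscle was 0.068. For 3 weeks over neonate the stricter filter gave MHC class II -0.0042, means over cells gave immune transcripts 0.40 and BMP antagonists 0.029, the mesenchymal classes gave posterior Hox -0.074 and glia and neuron transcripts 0.30, and without the minimum share BMP antagonists were 0.027, posterior Hox -0.059 and glia and neuron transcripts 0.34. For 4 over 3 weeks means over cells gave the citric acid cycle -0.0067, MHC class II -0.49 and the CXCL12 axis -0.089, no further filter gave haemoglobin 0.45, and the mesenchymal classes, with or without the minimum share, gave Wnt inhibitors 0.055 and glia and neuron transcripts 0.34.

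Ratios of epithelial class shares, cKO over control, were 1.18 for stem-like, 0.705 for colonocyte-like and 1.03 for goblet-like cells with the libraries clustered separately, the last on the other side of 1. They were 0.902 for colonocyte-like cells at a resolution of 0.5 and 0.987 for goblet-like cells with the stricter filter. Foxl1-high-like shares with the libraries clustered together were 19.4% in embryo, 2.76% in neonate, 11.9% at 3 weeks and 23.4% at 4 weeks. They were 0% in the embryo at a resolution of 0.5, 7.35% in embryo and 16.9% in neonate with no minimum share of markers, and 11.4% at 3 weeks and 22.7% at 4 weeks with the stricter filter.

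Cxcl12 in the Foxl1-high-like class over other mesenchymal classes was 2.45 in embryo, 1.47 at 3 weeks and 2.42 at 4 weeks with the libraries clustered together. With no minimum share it was 0.577 in embryo, on the other side of 1, and 2.02 in neonate. A marker threshold of 0.5 gave 1.54 in embryo and 1.11 at 3 weeks. No further filter gave 0.783 in neonate, 1.13 at 3 weeks and 2.15 at 4 weeks, the stricter filter 0.765, 1.48 and 2.25. Kept doublets gave 1.43 at 3 weeks and 2.12 at 4 weeks, and means over cells 1.22 and 2.38. A resolution of 0.5 gave 0.667 in neonate, and a resolution of 2 gave 0.830 in neonate, 1.37 at 3 weeks and 2.71 at 4 weeks.

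Cxcl12 in cells with over cells without a Foxl1 UMI was 1.41 in embryo, 0.948 at 3 weeks and 1.30 at 4 weeks over the mesenchymal classes. With at least 2 Foxl1 UMIs it was 1.42 in neonate, 0.927 at 3 weeks and 1.28 at 4 weeks. Means over cells gave 3.02 in embryo, 1.53 in neonate and 0.864 at 3 weeks, and CPM without abundant genes 0.859 at 3 weeks and 1.16 at 4 weeks. At 4 weeks it was 1.19 with no further filter and 1.19 with doublets kept. Cxcl12 at 4 weeks over embryo was 14.2 by TMM, 12.0 by means over cells, 5.98 over the mesenchymal classes and 5.93 over those named without the minimum share. Foxl1 was 1.98 by TMM and, on the other side of 1, 0.863 and 0.830 over the same sets of classes. The ratio of cells with a Cxcl12 UMI was 6.22 after thinning to 1000 UMIs and 3.23 after thinning to 4000.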

Other observations

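The explanations weighed in this part and their bounds were chosen only after the results were seen, except for the test on 7 clock genes. The cell filters and scalings drawn on here had been planned as alternatives. Some clusters were led by genes that no comparison describes. In the epithelium, 49 control and 41 cKO cells formed a cluster led by Cd74, H2-Aa and Il1b, genes of antigen-presenting cells. This cluster also held the stem markers Ascl2 and Cdca7 and stayed unnamed. Another, of 12 and 12 cells, was led by Fabp5, Ccl20 and Spib, genes known from the M cells that sample antigen over lymphoid follicles. A large unnamed cluster led by Fabp6 and the gasdermin genes Gsdmc2 and Gsdmc3 held 893 and 773. In the mesenchyme, 25 cells at 3 weeks were led by Chgb, Chga and Tph1, genes of enteroendocrine cells, although their markers gave them the name pericyte-like. At 4 weeks, 167 cells with a median of 2219 UMIs were led by immunoglobulin genes together with Krt5, Krt14 and Krt15, keratins of stratified epithelium.

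The mesenchyme at 3 and 4 weeks differed in genes of the circadian clock. Nr1d1, a clock repressor, was 19.8 CPM at 3 weeks and 2.30 CPM at 4 weeks, Per3 14.1 and 4.35 CPM and Tef 34.8 and 13.6 CPM, beside Dbp at 43.9 and 7.22 CPM. Arntl, an activator of the opposite phase, was 28.1 and 54.7 CPM, and Npas2 10.8 and 29.3 CPM. In the epithelium Nr1d1 was lower in cKO at a ratio of 0.588 and Dbp higher at 1.39. Nr1d2 (0.704), Tef (0.779), Per1 (0.821), Per3 (0.852) and Npas2 (0.884) were lower too, and Per2 (1.31) and Nfil3 (1.21) higher. Arntl (0.993) and Clock (1.04) lay near 1.

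The clock pattern was weighed against cell mix, time of collection and age. A different mix of cell classes was argued against by comparisons within named classes, of which 100% (42 of 42) kept the direction, over 7 genes picked because they differ. Of further clock genes Per1 kept it in 9 of 9 classes, Per2 in 4 of 4, Bhlhe41 in 2 of 2, Hlf in 5 of 7, Clock in 6 of 7 and Nfil3 in 5 of 8. Collection at another time of day was expected, before those genes were looked at, to place all of 7 further clock genes on the side of their arm, and 4 of 7 were there: Per1, Hlf, Ciart and Clock, but not Per2, Bhlhe41 or Nfil3, which speaks against the simplest form of the explanation, although a shift in which each gene follows its own phase was not tested and may still account for it. With 1 library per age, age and collection cannot be told apart.

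Higher cholesterol synthesis genes in the cKO epithelium were weighed against cell mix and processing. A different mix of clusters would leave little within clusters, where the median was 0.32, above 0 in 19 of 22. This was smaller than the 0.43 over all cells, so the mix of clusters may account for part. The cell filter or the scaling did not remove it, with a lowest median of 0.40 and a highest of 0.46. A change of epithelial lipid synthesis with the loss of CXCL12 from Foxl1-expressing cells is a candidate explanation, but with 1 library per genotype, genotype and animal or collection cannot be told apart. The epithelial libraries also differed in clock genes, and a difference in time of collection was not tested for this list.

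Lower mitochondrially encoded genes in the cKO epithelium were weighed against damaged cells and cell mix. If more damaged cells in the control were the whole cause, the stricter filter, with its limit of 10% mitochondrial UMIs, should bring the median above -0.1. The median was -0.17, against -0.30 with no filter. This limit cuts cells on the same UMIs that the list counts. It can move the median whatever the cause, so it cannot decide on damage, which may account for part. Within clusters the median was -0.12, below 0 in 20 of 22, close to the bound of -0.1 and nearer 0 than the -0.22 over all cells, so the mix of clusters may account for part as well. A difference by genotype itself stays open and was not tested.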
